A study of Homo sapiens with 18 samples.

How the data were processed

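RNA was profiled on 18 Affymetrix whole-transcript gene arrays from NB4 cells, an established human line from acute promyelocytic leukemia. Per the labels, wild-type cells and cells called TG2 knockout were left untreated or given 1 µM all-trans retinoic acid (ATRA) for 48 or 72 h. Each of the 6 groups held 3 biological replicates, and no array was left out. The labels give no date, scan batch or culture batch.

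The deposited table holds 1 value per probe set and array, on a scale taken here as log2. The scale is not stated in the sources used here. It was read from the values, which lie between 0.73 and 13.56 with 2 decimals. The authors' background correction, normalization and summary over probes are not given in the sources used here. Array medians lie between 6.12 and 6.26, but the quantiles of the arrays are not identical. No further normalization was applied for the reported values. No background measure or detection call was used, so the number of arrays and the spread between them limit the precision.

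Of 33297 probe sets, 19460 are annotated to exactly 1 gene, 1754 to several genes and 12083 to none. They cover 18418 genes with a probe set of their own. The 18 values of 974 probe sets equal those of another probe set, so a count of probe sets is not a count of genes. Genes named here come only from probe sets of a single gene, and a gene with several such probe sets is given by the one with the highest mean. Genes picked for the largest changes are instead given by their called probe set with the largest change. Entrez identifiers of 19429 single-gene probe sets matched the gene table, and no symbol had to be updated.

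A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, followed by eBayes with a mean-variance trend. Contrasts compared the genotypes untreated, at 48 h and at 72 h, each ATRA time with untreated cells in each genotype, and the responses of the genotypes with each other at both times. Adjusted p is the Benjamini-Hochberg value over all 33297 probe sets within a contrast. A probe set was called at an adjusted p under 0.05, and calls of at least 2-fold were counted as well. All tests were 2-sided. The fit assumes a common spread in all groups. The median SD between arrays was 0.0757 in untreated wild-type and 0.0985 in untreated knockout cells, against 0.216 to 0.243 in the ATRA groups.

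Before the data were examined, 20 gene lists with 380 genes were fixed, of which 349 had a probe set of their own. They cover azurophil granule, specific and gelatinase granule, NADPH oxidase, neutrophil receptors, chemokines and cytokines, chemokine and cytokine receptors, retinoid targets, interferon response, NF-kB targets, mitosis, DNA replication, MYC and ribosome biogenesis, progenitor, phagocytosis of dying cells, integrin adhesion and matrix, and the transglutaminase family. Markers of monocytes and macrophages, of eosinophils, basophils and mast cells, of erythroid cells and megakaryocytes, and of lymphocytes were listed too. Lists were tested with limma's camera at a preset correlation of 0.01, with adjusted p over the 20 lists of a contrast. They were tested again with the correlation estimated from each list's residuals, and with fry. Counts of list members were also taken with p adjusted over the list alone.

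The rule for named genes was fixed before the data were examined. It takes TGM2 in every comparison. For the genotype comparisons and for ATRA in wild-type cells it takes the 5 highest and 5 lowest changes among called probe sets of a single gene whose groups do not overlap. Symbols of unnamed or small RNA genes were passed over. For each difference of response it takes 4 in each direction. For each list it takes up to 4 called members with the largest change, or the 2 with the smallest p where none was called.

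Whether replicate numbers pair the arrays was tested by correlating the deviations of same-numbered arrays from their group means across probe sets. Only at 72 h did same-numbered arrays of both genotypes deviate together for each number, with r of 0.103, 0.16 and 0.138 across probe sets, above the values for unlike numbers. At 48 h r was 0.196 and 0.194 for numbers 1 and 2, also above unlike numbers. For number 3 it was 0.089, against 0.0936 for an unlike number, so pairing at 48 h stays open. On the second principal component (6.68% of the variance) number 2 was negative in every ATRA group (−58.4 to −11.1). Number 3 was positive in each (11.8 to 23.6). Number 1 read −1.2 (wild-type) and −12.9 (knockout) at 48 h, and 20.9 and 44.7 at 72 h. Arrays of numbers 2 and 3 thus shared a deviation at both times. The replicate number as a block was given beside the 72 h comparison, and its count at 48 h is given below.

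Alternatives were quantile normalization, centring of each array on its median, leaving out the dimmer probe sets, probe sets of 1 gene only, eBayes without trend, robust eBayes, the replicate block, only the compared groups in the fit, and leaving out each array in turn. Weights per group, and the replicate block within the 72 h arrays, were chosen after seeing the data. Splits of the arrays into other groups were counted, with at most 100 per comparison.

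The fit was tested on simulated data with the spread of each group and 200 changed probe sets, in 20 simulations per comparison. Each probe set was drawn on its own, without the deviations that arrays share over probe sets. Shares of false calls may therefore differ in the real data. In the untreated comparison the fit recovered 75.3% of 2-fold changes, and 0.118% of the calls were false. At 48 h between genotypes it recovered 78.6%, and 50.6% of the calls were false. At 72 h it recovered 74.8%, and 34.2% of the calls were false. For ATRA in wild-type cells 7.27% of the calls were false at 48 h and 5.7% at 72 h, and in knockout cells 16.8% and 9.75%. For the differences of response the fit recovered 32.9% of 2-fold changes at 48 h and 30.4% at 72 h. A fit of only the compared groups recovered 99.2% of 2-fold and 83.1% of 1.5-fold changes in the untreated comparison, where the fit of all arrays recovered 15.6% of the latter, with 16.8 false calls on average against 0.15. At 48 and 72 h between genotypes it recovered 38.4% and 46% of 2-fold changes, with 10.8 and 12 false calls on average against 140 and 68.6.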

Results

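Transcripts were measured in 6 groups of NB4 cells, with 3 arrays each: wild-type and TG2 knockout cells that were untreated or had received 1 µM ATRA for 48 or 72 h. NB4 is an acute promyelocytic leukemia line that differentiates towards neutrophil-like cells under ATRA, a ligand of retinoic acid receptors. TG2 is transglutaminase 2, a protein-crosslinking enzyme encoded by TGM2. The titles call the modified line a knockout, while its sample codes carry the letters KD. The 3 arrays of untreated wild-type cells correlated across probe sets with r between 0.9966 and 0.9969, and those of the ATRA groups with r between 0.9656 and 0.9788. The first principal component, which separated ATRA from untreated arrays, held 57.1% of the variance. On it wild-type 48 h replicate 1, knockout 48 h replicates 1 and 3 and knockout 72 h replicate 2 (17.5, 31.2, 31.1 and 30.0) lay nearer the untreated arrays (−89.9 to −84.7) than the other ATRA arrays did (46.3 to 56.6).

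What ATRA changes in wild-type cells was asked first. TGM2 had the largest rise among called probe sets of a single gene. Its log2 signal went from 6.43 ± 0.17 (SD, n = 3) to 12.27 ± 0.18 at 48 h and 12.37 ± 0.18 at 72 h, a rise of 57.3-fold and 61.7-fold (adjusted p = 8.54e-12 and 4.66e-12). BPI, a bactericidal protein of neutrophil granules, rose 44.2-fold at 48 h and 55.6-fold at 72 h. ALOX5AP, which serves leukotriene synthesis, rose 22.9-fold and 26.5-fold. CCL24, a chemokine for eosinophils, rose 22.9-fold and 23.6-fold, and the Src family kinase FGR 18.3-fold and 20.3-fold. CYTL1, a small secreted protein, fell most among them, with log2 changes of −5.26 ± 0.14 (SE) at 48 h and −5.08 ± 0.14 at 72 h. LYZ, which encodes lysozyme, changed by −3.58 and −3.67, and the transcription factor EBF3 by −3.53 and −3.67. VIM, which encodes the filament protein vimentin, changed by −3.65 ± 0.55 at 48 h, and HDC, which makes histamine, by −3.56. At 72 h MS4A3 changed by −3.78 and PRG2, an eosinophil granule protein, by −3.72. The rule for named genes took only those in which the ATRA arrays did not overlap the untreated ones, so the lack of overlap is no separate result.

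In all, limma called 12950 probe sets at 48 h, 6428 higher and 6522 lower, and 14666 at 72 h, 7679 higher and 6987 lower. Of these, 4374 and 5272 changed at least 2-fold. The calls covered 7290 genes at 48 h and 8204 at 72 h. The median change over all probe sets was 0.10 at 48 h and 0.12 at 72 h. Between 48 and 72 h limma called 0 probe sets in wild-type cells (1952 at an unadjusted p under 0.05) and 0 in knockout cells (2732).

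Retinoid targets and interferon response genes rose together. At 72 h in wild-type cells 18 of 22 measured retinoid targets were higher and 1 lower, with the same counts adjusted over the list alone. The median log2 change was 1.42 (camera adjusted p = 1.33e-09), and the call held with an estimated correlation (adjusted p = 0.028). Its members included DHRS3, a retinaldehyde reductase, at 3.92, ASB2 at 3.36, PRAM1 at 3.28 and TNFAIP2 at 2.78. Of the interferon response genes, 24 of 29 were higher and 0 lower (the same adjusted over the list alone), with a median of 1.28 (adjusted p = 1.47e-08, and 0.322 with an estimated correlation). OAS3, an antiviral nucleotide synthetase, changed by 3.18, TRIM22 by 2.67, the transcription factor IRF1 by 2.60 and OAS1 by 2.40. The interferon mean of replicate 2 of the 72 h wild-type arrays, 0.65 above untreated, lay far below the 1.71 and 1.61 of the others.

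Surface and adhesion genes of mature myeloid cells rose as lists too. Neutrophil receptors had 15 of 26 members higher and 1 lower, also adjusted over the list alone, with a median of 0.88 (adjusted p = 4.48e-05, and 0.326 with an estimated correlation). ICAM1, an adhesion molecule, changed by 3.49, CSF3R, the receptor of granulocyte colony-stimulating factor, by 2.33, and the integrin chains ITGAM and ITGAX by 2.32 and 2.30. Integrin adhesion and matrix had 11 of 19 members higher and 1 lower, also adjusted over the list alone, with a median of 0.57 (adjusted p = 0.000118, and 0.221 with an estimated correlation). ITGB7 changed by 2.66 and PXN, which encodes the focal adhesion protein paxillin, by 2.29. Monocyte and macrophage markers had 9 of 18 members higher and 1 lower, also adjusted over the list alone, with a median of 0.38 (adjusted p = 0.0115, and 0.322 with an estimated correlation). Their changes were small: VSIG4 0.98, CD68 0.85, CSF1R 0.79 and SIGLEC1 0.76.

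Signalling lists were mixed at 72 h in wild-type cells. Chemokines and cytokines had 13 of 30 members higher and 3 lower, also adjusted over the list alone, with a median of 0.52 (adjusted p = 0.0409, and 0.445 with an estimated correlation). Beside CCL24, CCL2 rose by 1.70, whereas the inflammatory cytokine TNF changed by −1.75 and the death ligand TNFSF10 by −1.65. The camera call of this list ended without replicate 1 or without replicate 3 of the 72 h wild-type arrays, and with quantile normalization. NF-kB targets had 7 of 22 members higher and 1 lower, and 6 higher and 1 lower adjusted over the list alone, with a median of 0.50 (adjusted p = 0.0357, and 0.507 with an estimated correlation). ICAM1, CXCL8 at 1.51 and the inhibitor TNIP1 at 1.28 were higher, and TNF was lower. This call also ended without either of these replicates. In the transglutaminase family 3 of 9 members were higher and 0 lower, also adjusted over the list alone: TGM2, TGM3 at 1.26 and TGM5 at 0.55 (median 0.17, adjusted p = 0.0295, and 0.221 with an estimated correlation). Fitting only the compared arrays ended that call.

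Proliferation genes fell under ATRA. Of the mitosis genes 19 of 24 were lower at 72 h and 0 higher, with a median of −0.89 (adjusted p = 8.92e-07, and 0.349 with an estimated correlation). CENPE, a kinetochore motor, changed by −1.87, the checkpoint kinase BUB1B by −1.50, KIF20A by −1.46 and CENPF by −1.42. DNA replication had 16 of 27 members lower and 1 higher, with a median of −0.69 (adjusted p = 0.000102, and 0.445 with an estimated correlation). GINS2, part of the replicative helicase, changed by −2.53, the cyclins CCNE2 and CCNE1 by −2.52 and −1.22, and DTL by −1.40. In MYC and ribosome biogenesis 13 of 17 members were lower and 0 higher, with a median of −0.89 (adjusted p = 7.65e-06, and 0.328 with an estimated correlation). UTP20 and POLR1B, which serve ribosomal RNA processing and transcription, changed by −2.09 and −2.06, NOLC1 by −1.30 and PNO1 by −1.20. Adjusted over the list alone, the counts were the same for mitosis and replication, and 14 members were lower in the MYC list.

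The granule lists moved in both directions and were not called as lists at 72 h. Azurophil granule had 7 of 13 members higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.523). BPI, SERPINB1 at 3.01 and DEFA4 at 2.75 were higher, and LYZ was lower. Specific and gelatinase granule had 6 of 16 members higher and 2 lower, and 8 higher and 2 lower adjusted over the list alone (adjusted p = 0.22). The collagenase MMP8 changed by 2.20, CRISP3 by 2.04 and OLFM4 by 1.16, against −3.17 for the gelatinase MMP9. NADPH oxidase had 4 of 8 members higher and 1 lower, also adjusted over the list alone (adjusted p = 0.1). CYBA and CYBB, the membrane chains of the oxidase, changed by 1.62 and 1.36, RAC2 by 0.62 and NCF4 by −0.81.

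The remaining lists were not called at 72 h in wild-type cells. Progenitor genes had 2 of 12 members higher and 4 lower (adjusted p = 0.246), with BCL2 at −2.01, WT1 at −1.91, MYB at −1.15 and MEIS1 at 0.75. Phagocytosis of dying cells had 6 of 21 members higher and 5 lower (adjusted p = 0.826). The receptor MERTK changed by 2.72, P2RY2 by −2.07, ANXA1 by −1.92 and STAB1 by −1.51. Chemokine and cytokine receptors had 8 of 20 members higher and 3 lower (adjusted p = 0.0527), with CCR1 at 1.95, IL10RA at 1.85, CX3CR1 at 1.73 and IL17RA at −2.10. Eosinophil, basophil and mast cell markers had 2 of 9 members higher and 3 lower (adjusted p = 0.377). PRG2, HDC at −3.63 and EPX at −1.72 were lower, CLC was higher at 1.45, and the median of 0.21 had another sign than the mean of −0.69. Erythroid and megakaryocyte markers had 3 of 11 members higher and 0 lower (adjusted p = 0.102), with ALAS2 at 0.60, PPBP at 0.55 and ITGA2B at 0.35. Lymphocyte markers had 6 of 13 members higher and 2 lower (adjusted p = 0.105), with NKG7 at 1.07, CD79A at 0.85, and CD3D and CD79B both at −0.73. Adjusted over the list alone, 6 phagocytosis genes were lower, 2 erythroid markers were higher, and 8 lymphocyte markers were higher and 3 lower.

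At 48 h camera called 8 of the 20 lists in wild-type cells, 5 higher and 3 lower. The call of DNA replication, among the lower ones, ended with quantile normalization and with brighter probe sets only. Retinoid targets had a median of 1.33 (adjusted p = 7.07e-09, and 0.0374 with an estimated correlation) and interferon response genes 0.90 (adjusted p = 3.67e-06, and 0.439 with an estimated correlation). Mitosis genes had a median of −0.83 (adjusted p = 1.73e-05, and 0.439 with an estimated correlation).

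The same ATRA comparison in TG2 knockout cells gave a response of the same kind. TGM2 itself rose in the knockout, 23.6-fold at 48 h and 28.9-fold at 72 h (adjusted p = 1.21e-10 and 5.95e-11), and stood at percentile 96.9 and 97.6 of all probe sets. The transcript was thus not absent under ATRA, which goes against the name knockout if that means loss of the transcript. TG2 protein was not measured here. BPI rose 27.2-fold and 36-fold, ALOX5AP 18.9-fold and 22.4-fold, CCL24 11.2-fold and 8.98-fold, and FGR 15-fold and 18.9-fold. CYTL1 changed by −4.80 and −4.96, LYZ by −3.60 and −3.35 and EBF3 by −3.27 and −3.56. VIM and HDC changed by −3.96 and −3.42 at 48 h, and MS4A3 and PRG2 by −2.81 and −3.22 at 72 h.

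In the knockout limma called 13783 probe sets at 48 h, 7148 higher and 6635 lower, and 13996 at 72 h, 7594 higher and 6402 lower. At least 2-fold changes made up 4284 and 4603 of them. At 48 h 4723 probe sets were called higher in both genotypes, 5612 lower in both and 1 in opposite directions. Independent calls would give 1380 and 1300. At 72 h the counts were 5427, 5577 and 2, where independent calls would give 1751 and 1343. The calls of both genotypes use the same estimate of spread per probe set, so they are not independent. Of the probe sets changed at least 2-fold in wild-type cells, 99.31% at 48 h and 99.13% at 72 h had the same sign in the knockout. Across probe sets, which are not independent replicates, the changes of the genotypes correlated with r of 0.909 and 0.896.

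**Figure D1:**
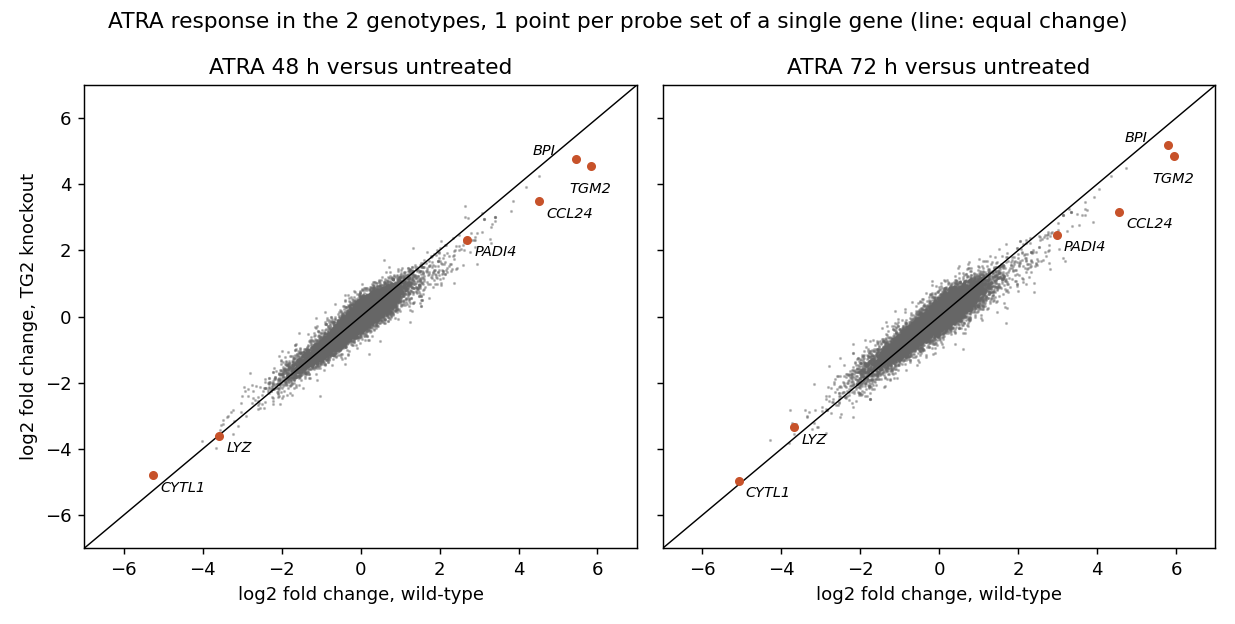
Each point is a probe set of a single gene, with its log2 change under ATRA in wild-type cells on the x axis and in TG2 knockout cells on the y axis, at 48 h (left) and 72 h (right), each the difference of means of 3 arrays. Points follow the line of equal change, and TGM2 (5.84 and 4.56 at 48 h) and CCL24 (4.52 and 3.48 at 48 h) lie below it.

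At 72 h in the knockout camera called 7 lists. The call of MYC and ribosome biogenesis, a lower one, ended with quantile normalization and with brighter probe sets only, as it did at 48 h. Retinoid targets had 15 of 22 members higher and 1 lower, and 16 higher and 1 lower adjusted over the list alone, with a median of 1.14 (adjusted p = 1.62e-08, and 0.0434 with an estimated correlation). Mitosis had 18 of 24 members lower, also adjusted over the list alone, with a median of −0.94 (adjusted p = 8.79e-07, and 0.499 with an estimated correlation). Of the interferon response genes 10 of 29 were higher and 1 lower, and 9 higher and 1 lower adjusted over the list alone, with a median of 0.50 (adjusted p = 0.00186, and 0.499 with an estimated correlation). IRF1 changed by 2.34, TRIM22 by 1.95 and OAS3 by 1.68.

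Whether the lines differ before ATRA was tested in untreated cells. TGM2 did not differ detectably: 6.39 ± 0.11 (SD, n = 3) in the knockout and 6.43 ± 0.17 in wild-type cells, a difference of −0.04 ± 0.19 (SE, adjusted p = 1). Both values lie at percentile 54.1 of probe sets. STAP1, a signalling adaptor, was 2.53-fold higher in the knockout, at 6.51 ± 0.13 against 5.17 ± 0.08 (log2 difference 1.34 ± 0.18 SE, adjusted p = 0.0197). SLCO3A1, an organic anion transporter, was lower, at 7.66 ± 0.04 against 8.82 ± 0.02 (−1.16 ± 0.13, adjusted p = 0.00243). These were the only calls of the fit to all 18 arrays, with 382 probe sets at an unadjusted p under 0.05. The chemokine gene CCL2 read 8.58 ± 0.05 in the knockout and 9.55 ± 0.05 in wild-type cells and missed the threshold (−0.98 ± 0.22 SE, adjusted p = 0.723).

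The count in untreated cells depended on which arrays set the spread. With only the 6 untreated arrays limma called 284 probe sets, 124 higher and 160 lower, and CCL2 then passed (adjusted p = 0.00019). With weights per group, chosen after seeing the data, it called 309. The SLCO3A1 call held under every alternative, while the STAP1 call ended when any 1 of the 6 untreated arrays was left out (adjusted p up to 0.268), with quantile normalization and with the replicate block. Groups did not overlap in 18.1% of probe sets, where chance gives 10%. Camera called 0 of 20 lists (6 at an unadjusted p under 0.05), also with an estimated correlation, and fry called 0. At the preset correlation and with only the 6 untreated arrays camera called 3 lower in the knockout, NF-kB targets (median −0.077), NADPH oxidase (−0.11) and chemokines and cytokines (−0.04). With brighter probe sets it called 6 lower, NF-kB targets and chemokines and cytokines again, specific granule, and the eosinophil, erythroid and lymphocyte markers.

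At 48 h of ATRA the TGM2 transcript was lower in the knockout than in wild-type cells, at 10.95 ± 0.37 (SD, n = 3) against 12.27 ± 0.18. The difference was −1.31 ± 0.19 (SE, adjusted p = 0.0345), so the knockout held 40.2% of the wild-type signal (95% interval 31.1% to 52%). This interval rests on the spread shared by all groups. The untreated arrays vary less than those of 48 h, so it is likely too narrow. IGF2BP2, an RNA-binding protein, was higher in the knockout by 1.13 ± 0.18 and CA2, a carbonic anhydrase, by 0.87 ± 0.14 (adjusted p = 0.047 for each). PADI4, which citrullinates histones, was lower by −0.80 ± 0.12 (adjusted p = 0.0446), and MRPL49, a protein of the mitochondrial ribosome, by −0.94 ± 0.15 (adjusted p = 0.047). With 2 probe sets of no gene, these were all 7 calls, 3 higher and 4 lower, and 1972 probe sets had an unadjusted p under 0.05. Leaving out any of wild-type replicates 1, 2 and 3 or knockout replicate 1 or 2 ended the TGM2 call (adjusted p up to 0.997), with the difference between −1.48 and −1.12. The calls of IGF2BP2, CA2, PADI4 and MRPL49 also ended without any 1 of the wild-type arrays.

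No call at 48 h withstood every alternative. Limma called 0 probe sets with only the 48 h arrays or with weights per group, and the TGM2 call was kept in 7 of 15 alternatives. Simulated data with the spread of these groups and no difference gave 49.8 calls on average and 97 at most, more than the 7 found. Each probe set was simulated on its own, so these counts need not describe chance in the real arrays.

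At 72 h TGM2 again read lower in the knockout, at 11.24 ± 0.37 against 12.37 ± 0.18. The difference was −1.13 ± 0.19 (SE, adjusted p = 0.0267), or 45.7% of the wild-type signal (95% interval 35.4% to 59%). This interval was made in the same way and is likely too narrow as well. SLC7A2, a transporter of cationic amino acids, was 2.83-fold higher in the knockout (1.5 ± 0.26, adjusted p = 0.0374), and IGF2BP2 was 2.71-fold higher (1.44 ± 0.18, adjusted p = 0.00408). STAP1 was higher by 1.27 ± 0.18 (adjusted p = 0.00968), CA2 by 0.88 ± 0.14 (adjusted p = 0.0162) and RPF2, a ribosome assembly factor, by 0.86 ± 0.12 (adjusted p = 0.00801). The other called probe set of RPF2 read 0.59 ± 0.11 higher (adjusted p = 0.0483). Lower in the knockout were CCL24 (−1.36 ± 0.23, adjusted p = 0.0239), PADI4 (−0.94 ± 0.12, adjusted p = 0.00438), the adhesion molecule SELP (−0.94 ± 0.15, adjusted p = 0.0165) and SIGLEC12, a sialic acid-binding lectin (−0.90 ± 0.16, adjusted p = 0.0461). TNFAIP2 of the retinoid list was also lower (−0.89 ± 0.11, adjusted p = 0.00408). PADI4 and CCL24 had risen under ATRA in both genotypes, and CA2 had fallen from 8.21 to 5.97 in wild-type cells.

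**Figure D2:**
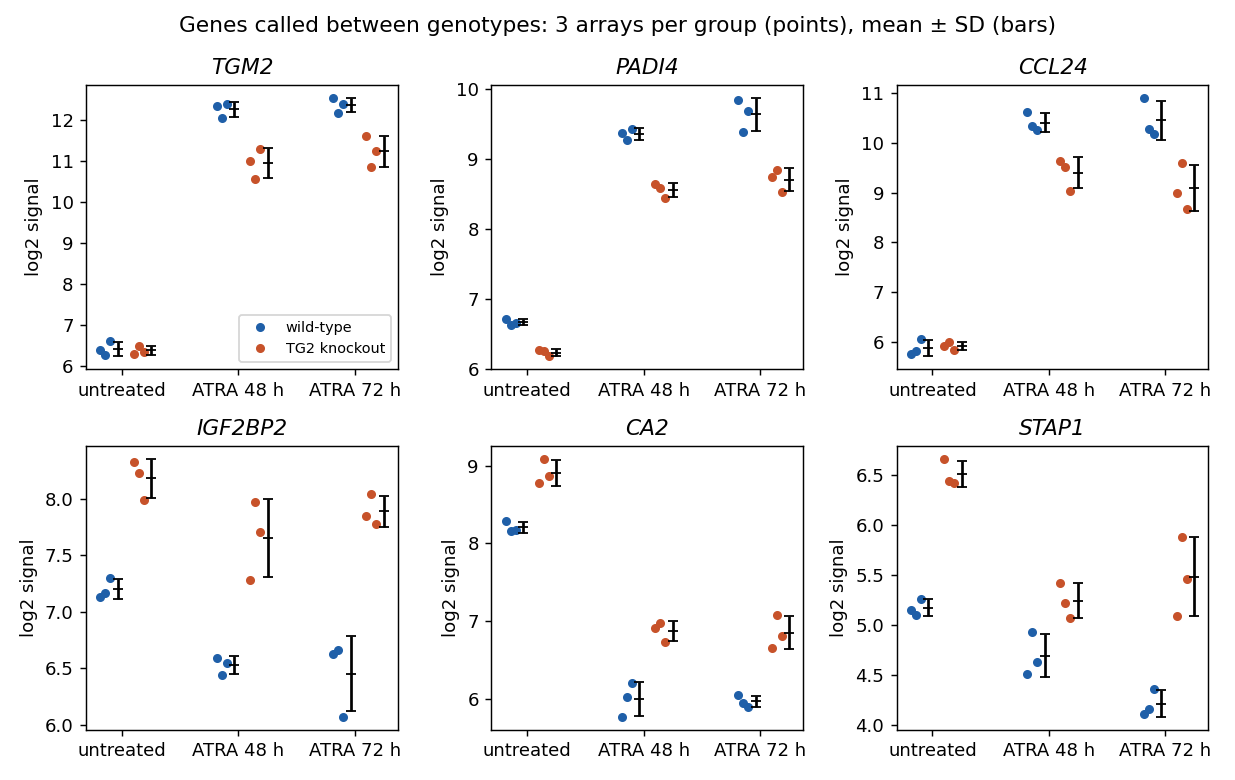
Log2 signal of 6 genes called between the genotypes, with 1 point per array (3 per group) and bars for the mean and SD, in wild-type (blue) and TG2 knockout (orange) cells. TGM2 reads alike in untreated cells (6.43 and 6.39) and apart at 48 h (12.27 and 10.95), while IGF2BP2, CA2, STAP1 and PADI4 are already apart in untreated cells.

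In all, 32 probe sets were called at 72 h, 15 higher and 17 lower, and 3713 had an unadjusted p under 0.05. They hold 19 probe sets of a single gene, which stand for 18 genes, 8 of several genes and 5 of none. TGM2, PADI4, IGF2BP2 and CA2 were called at both 48 and 72 h with the same sign. Independent calls would share 0.0034 probe sets, but both comparisons use the same estimate of spread per probe set. IGF2BP2, CA2 and PADI4 also read apart in untreated cells (0.983, 0.70 and −0.433), so 0.0034 does not measure chance. Across all probe sets the genotype differences at 48 and 72 h correlated with r = 0.114, and with r = 0.297 among probe sets above the median level. Groups did not overlap in 6.76% of probe sets at 48 h and 11.6% at 72 h, where chance gives 10%.

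The count at 72 h rested on single arrays and on the shared spread. Among the named genes IGF2BP2, PADI4, RPF2 and TNFAIP2 kept their calls when any 1 of the 6 arrays at 72 h was left out. The TGM2 call ended without wild-type replicate 1 or 3 or knockout replicate 2 or 3, its difference staying between −1.31 and −0.94. With the replicate number as a block it was 29, and the calls of SLC7A2 and SIGLEC12 ended. It was 0 with only the 72 h arrays, with or without the block, and 14 with weights per group. Without wild-type replicate 1 it was 11, and without wild-type replicate 2 it was 126. Simulated data without any difference gave 14.6 calls on average and 38 at most, so the count of 32 lies within that range. The simulations hold no pairing and no deviations shared over probe sets, so that range need not describe chance in the real arrays. Other splits of the 72 h arrays called at most 1 where they parted all 3 number pairs, and up to 52 where they did not. Few splits part all 3 pairs, so this contrast cannot exclude chance.

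Several lists differed between the genotypes at 72 h by camera, 11 lower in the knockout and 1 higher. Of the 29 interferon response genes all had a negative difference, with a median of −0.60 (adjusted p = 3.76e-15, and 0.104 with an estimated correlation). This median moved to −0.93 without wild-type replicate 2 and to −0.42 without wild-type replicate 1. None passed over all probe sets, and 8 were lower adjusted over the list alone. IFI6 and OAS2 had the smallest p, at −1.28 ± 0.28 and −1.36 ± 0.33 (adjusted p = 0.108 and 0.134). Relative to untreated wild-type cells the list means of the wild-type arrays were 1.71, 0.65 and 1.61, and those of the knockout arrays 0.80, 0.41 and 0.62, so 1 wild-type array fell among the knockout arrays. MYC and ribosome biogenesis was the list called higher, with all 17 members positive and a median of 0.35 (adjusted p = 1.32e-07, and 0.177 with an estimated correlation). DKC1 and RRP9 of this list read 0.42 ± 0.11 and 0.46 ± 0.15 higher (adjusted p = 0.164 and 0.239), and 3 members were higher adjusted over the list alone.

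**Figure D3:**
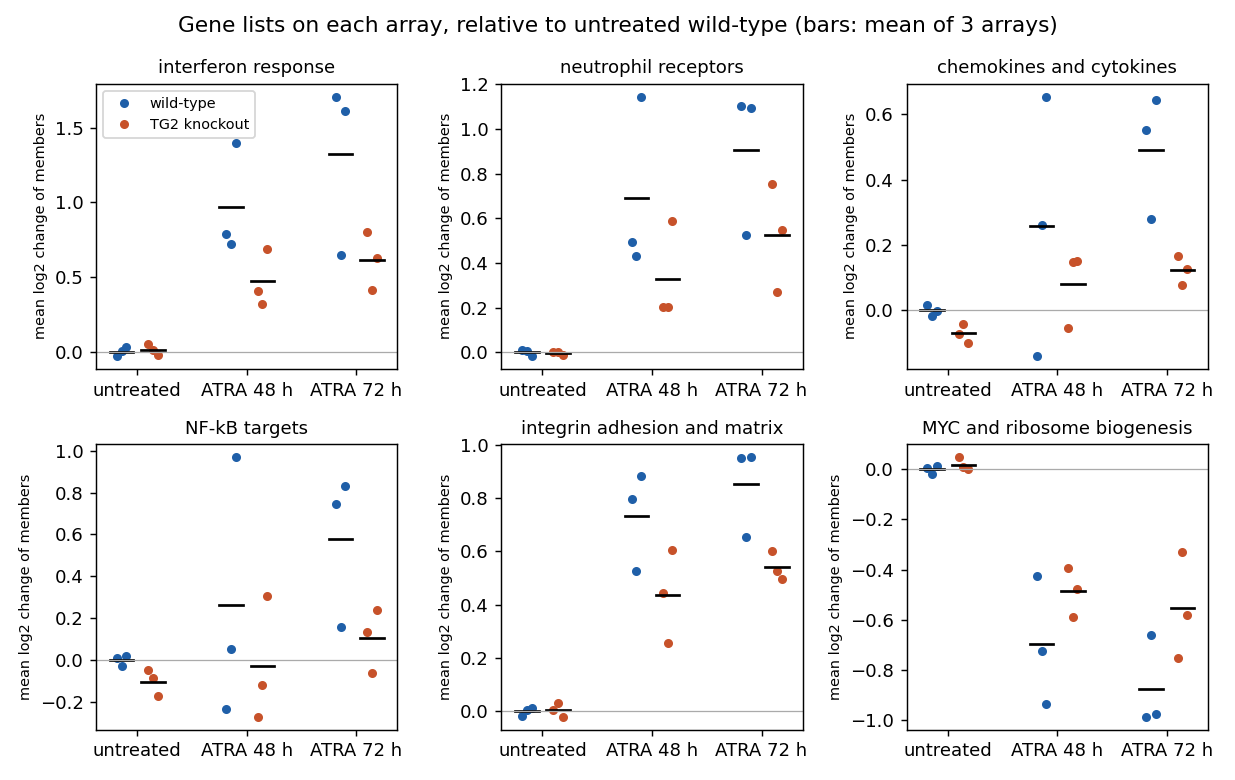
Mean log2 change of the members of 6 gene lists on each array, relative to the untreated wild-type mean, for wild-type (blue) and TG2 knockout (orange) cells, with bars at the mean of 3 arrays. Interferon response at 72 h reads 1.71, 0.65 and 1.61 on the wild-type arrays and 0.80, 0.41 and 0.62 on the knockout arrays.

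Lists of leukocyte function were called lower in the knockout at 72 h. NF-kB targets had a median of −0.49 (adjusted p = 3.85e-06, and 0.268 with an estimated correlation), neutrophil receptors −0.39 (adjusted p = 3.85e-06, and 0.177 with an estimated correlation), and chemokines and cytokines −0.29 (adjusted p = 1.32e-05, and 0.104 with an estimated correlation). Integrin adhesion and matrix had a median of −0.25 (adjusted p = 0.000152, and 0.104 with an estimated correlation), and monocyte and macrophage markers −0.19 (adjusted p = 4e-04, and 0.104 with an estimated correlation). NADPH oxidase had a median of −0.26 (adjusted p = 0.00828, and 0.279 with an estimated correlation), and chemokine and cytokine receptors −0.21 (adjusted p = 0.00136, and 0.303 with an estimated correlation). Specific and gelatinase granule had −0.20 (adjusted p = 0.00986), retinoid targets −0.17 (adjusted p = 2.53e-05) and the transglutaminase family −0.19 (adjusted p = 0.00525), each with an adjusted p of 0.101 with an estimated correlation. TGM2 itself belongs to the transglutaminase list. NADPH oxidase and monocyte markers already had medians of −0.11 and −0.07 in untreated cells (unadjusted p = 0.0416 and 0.0111). NF-kB targets and chemokines and cytokines also had lower medians there, as given above. The differences of response at 72 h were −0.03 for NADPH oxidase (adjusted p = 0.17) and −0.07 for monocyte markers (adjusted p = 0.0358). The monocyte call was lost in 8 of 23 alternatives, an estimated correlation and fry among them. Over the alternatives the medians ranged from −0.70 to −0.34 for NF-kB targets, from −0.60 to −0.25 for neutrophil receptors and from −0.55 to −0.21 for chemokines and cytokines, and that of the MYC list from 0.21 to 0.46. They ranged from −0.315 to −0.108 for NADPH oxidase, from −0.379 to −0.124 for chemokine and cytokine receptors and from −0.405 to −0.141 for monocyte markers.

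Members of these lists passed over all probe sets only for TGM2, CCL24 and TNFAIP2. Adjusted over the list alone, 6 chemokines and cytokines, 5 integrin genes, 4 neutrophil receptors, 4 NF-kB targets, 2 monocyte markers, 2 retinoid targets, 2 chemokine and cytokine receptors and 1 NADPH oxidase gene were lower. Of the specific granule genes 1 was higher and 1 lower, and of the transglutaminases 1 was lower. ITGAM read −0.71 ± 0.18 (adjusted p = 0.145), ITGAX −0.87 ± 0.25 (adjusted p = 0.212), CSF1R, a growth factor receptor of macrophages, −0.95 ± 0.21 (adjusted p = 0.099), MMP8 −1.32 ± 0.30 (adjusted p = 0.114) and TNF −0.87 ± 0.21 (adjusted p = 0.134). Mitosis and DNA replication were not called, with medians of 0.00 and −0.01 (adjusted p = 0.961 and 0.681), but without knockout replicate 2 the mitosis median was −0.14 and was called. The calls of NADPH oxidase (without wild-type replicate 1 or knockout replicate 2), specific granule (without wild-type replicate 3, and with brighter probe sets only at a median of −0.12) and chemokine and cytokine receptors (without knockout replicate 2) also rested on single arrays. With an estimated correlation 0 lists were called, 7 having an unadjusted p under 0.05, and fry called 7.

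At 48 h camera called 9 lists between the genotypes, 8 lower and 1 higher. Interferon response genes had a median of −0.45, with 1 of 29 members positive (adjusted p = 6.9e-11, and 0.355 with an estimated correlation). Neutrophil receptors had −0.35 (adjusted p = 1.18e-07, and 0.355 with an estimated correlation), and the chemokine receptor CXCR2 among them read −0.70 ± 0.13 (adjusted p = 0.164). Integrin adhesion and matrix had −0.34 (adjusted p = 1.41e-05, and 0.331 with an estimated correlation), and MYC and ribosome biogenesis 0.20 (adjusted p = 4.47e-05, and 0.458 with an estimated correlation). With an estimated correlation 0 lists were called, 2 having an unadjusted p under 0.05, and fry called 0. Without replicate 3 of the 48 h wild-type arrays, camera called 5 lists, all lower. Interferon response (median −0.27), neutrophil receptors and integrin adhesion (both −0.14) were kept, mitosis and DNA replication (both −0.20) were new, and the MYC list and 5 others were no longer called. Among these, NF-kB targets (median 0.086) and chemokines and cytokines (0.055) changed sign.

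Whether the genotypes responded differently to ATRA was tested directly as the difference of responses. The TGM2 rise was smaller in the knockout by −1.28 ± 0.27 at 48 h (SE, adjusted p = 1) and −1.09 ± 0.27 at 72 h (adjusted p = 0.98), and neither passed the correction. CCL24 read −1.40 ± 0.32 at 72 h, ITGAM −0.97 ± 0.25 and TNFAIP2 −0.63 ± 0.16 (adjusted p = 0.98 for each). At 48 h limma called 1 probe set, of no annotated gene, and 960 had an unadjusted p under 0.05. At 72 h it called 0, with 1553 at an unadjusted p under 0.05 and 3 calls when only the 12 compared arrays were fitted. Camera called 6 lists at 48 h, 5 lower and 1 higher, and 10 at 72 h, 9 lower and 1 higher. Interferon response had a median of −0.48 at 48 h (adjusted p = 1.26e-08, and 0.527 with an estimated correlation) and −0.58 at 72 h (adjusted p = 7.7e-14, and 0.168 with an estimated correlation). Over the alternatives these medians ranged from −0.63 to −0.33 and from −0.97 to −0.36. With an estimated correlation 0 lists were called at either time.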

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

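The tests of differences between the lines before ATRA, of the TGM2 transcript in untreated cells, of quantile normalization, of exchanges within pairs and of splits that part the pairs were chosen only after the results they bear on had been seen.

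At 48 h 1 probe set of no annotated gene responded differently in the genotypes by a test of the difference of responses (log2 difference 2.87, knockout minus wild-type). Its group means lay between 1.83 and 4.01, low on the array's scale. The arrays of each time were split anew, mixing the genotypes, and 6 of 100 splits, the real one included, gave as many calls. Another split gave up to 12, so chance is not excluded. At 72 h the real count of 0 was met by 100 of 100 splits, with up to 18 calls in another. Camera called 6 lists at 48 h and 10 at 72 h. Of 100 splits, the real one included, 50 and 22 called as many, and others called up to 10 and 15 lists, so chance is not excluded for these either. These splits ignore the pairing of same-numbered arrays at 72 h. Of all 80 splits that part the 3 pairs of 72 h, 20, the real one included, called as many lists, with up to 13 in another. All 20 kept the 72 h arrays grouped by genotype and differed in the untreated arrays, whereas splits that mixed the genotypes at 72 h called up to 8. The number of lists at 72 h thus came with the grouping of the 72 h arrays, whichever way the untreated arrays were grouped, and does not set a difference of responses apart from a genotype difference at 72 h.

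The lists called for a difference of response at 48 h had median log2 differences of −0.44 for neutrophil receptors, −0.29 for chemokine and cytokine receptors, −0.12 for retinoid targets, −0.48 for interferon response, 0.19 for MYC and ribosome biogenesis, and −0.28 for integrin adhesion and matrix. At 72 h they were −0.39 for neutrophil receptors, −0.30 for chemokines and cytokines, −0.27 for chemokine and cytokine receptors, −0.26 for retinoid targets, −0.58 for interferon response, −0.36 for NF-kB targets, 0.30 for MYC and ribosome biogenesis, −0.24 for integrin adhesion and matrix, −0.15 for the transglutaminase family and −0.068 for monocyte and macrophage markers. Over the alternatives the medians ranged from −0.56 to −0.066 for neutrophil receptors, −0.43 to −0.08 for chemokine and cytokine receptors, −0.25 to −0.062 for retinoid targets, −0.63 to −0.33 for interferon response, 0.11 to 0.32 for the MYC list and −0.40 to −0.20 for integrin adhesion at 48 h. At 72 h they ranged from −0.97 to −0.36 for interferon response, −0.64 to −0.23 for NF-kB targets, −0.61 to −0.24 for neutrophil receptors, −0.46 to −0.21 for chemokines and cytokines and −0.31 to −0.045 for the transglutaminase family. With an estimated correlation none of them was called. Without wild-type 48 h replicate 3 the calls for neutrophil receptors, chemokine and cytokine receptors, retinoid targets and the MYC list at 48 h ended. That for retinoid targets also ended without knockout 48 h replicate 1 or 3 and with only the compared groups. Without wild-type 72 h replicate 3 the calls for the transglutaminase family, monocyte markers, NF-kB targets, and chemokine and cytokine receptors at 72 h ended. Those for the receptors (without knockout 72 h replicate 2), the transglutaminase family and monocyte markers (both without wild-type 72 h replicate 1, knockout 72 h replicate 1 or 2, or knockout untreated replicate 3) ended without other arrays too. The monocyte call, which ended without wild-type untreated replicate 3 as well, was lost in 8 of 23 alternatives, with medians from −0.41 to −0.024.

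In the genotype comparisons and in the ATRA comparisons, 3 arrays against 3 make 10 splits, which can never give a share under 0.1. The counts of splits below include the real one. Between genotypes the real split called 2 probe sets in untreated cells (1 split with as many, highest other 0), 7 at 48 h (2 splits with as many, highest other 872) and 32 at 72 h (2 splits with as many, highest other 52). It called 0 lists in untreated cells (10 splits with as many, highest other 1), 9 at 48 h (1 split with as many, highest other 8) and 12 at 72 h (2 splits with as many, highest other 14). The 4 ATRA comparisons called between 12950 and 14666 probe sets, each with 1 split as large and 0 in any other. The split with 872 calls set wild-type replicate 1 and knockout replicates 1 and 3 of 48 h against the rest, which points to a structure of these arrays other than genotype. On the first principal component these 3 arrays (17.5, 31.2 and 31.1) lay nearer the untreated arrays than the other 48 h arrays did (51.7 to 56.6). At 72 h 4 splits part all 3 number pairs: the real one called 32 probe sets and 12 lists, and the others at most 1 probe set and 6 lists. So few splits cannot exclude chance. The split with 52 calls keeps 2 pairs together and parts 1.

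The genes called between the genotypes at 72 h of ATRA were set against a difference of the lines that was present before ATRA. For IGF2BP2, CA2 and PADI4, called at both 48 and 72 h, the median untreated difference was 0.747 of the median 72 h difference, and all 3 passed in a fit of the untreated arrays alone. By gene the share was 0.684 for IGF2BP2 and 0.792 for CA2 but 0.463 for PADI4, which leaves PADI4 open. For the other 28 called probe sets without TGM2 the share was 0.179, and 7 of them, STAP1 among these, passed before ATRA in the same direction. These 28 were picked by their 72 h difference, which tends to raise it and so to lower the share. Some are also probe sets of the same genes. The low share therefore does not decide whether such a difference was their cause. STAP1 and SLCO3A1 differed before ATRA, where TGM2 differed by −0.037 and lay near the middle of all probe sets, so a loss of TGM2 transcript there cannot be told apart from no loss. The genotype itself and differences between lines grown apart stay open, since 1 knockout line stands against 1 wild-type line.

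The lower interferon response list of the knockout at 72 h (median −0.60) was set against 3 technical explanations. After quantile normalization the median was −0.64 and the list stayed called, which argues against unequal signal ranges as the cause. Among 10000 random lists matched on the wild-type 48 h response and on level the list lay at percentile 0 (random median −0.12, lowest −0.37). Genes matched in this way thus differed less than the list did. Random lists lack the variation that interferon genes share, and the 72 h response was not matched. A smaller ATRA response of all genes is therefore not excluded by this test. An exact permutation test of array means over 48 and 72 h gave p = 0.02, but the list was picked from 20 and its adjusted p was 0.1, which the prediction had not allowed for. At 72 h 1 wild-type array, replicate 2 with a list mean of 0.65, lay among the knockout arrays at 0.80, 0.41 and 0.62. Its same-numbered knockout array was the lowest of these, and the knockout was lower in all 3 pairs, by differences of −0.91, −0.24 and −0.98. An exact permutation test that exchanged the genotypes only within these pairs at 72 h, and freely at 48 h, gave p = 0.0125, the smallest that 160 arrangements allow, and 0.0833 adjusted over the lists. With exchanges only within pairs at both times the exact test gave p = 0.0312, the smallest that 64 arrangements allow, and 0.0568 adjusted over the lists. Differences between cultures therefore cannot be told apart from genotype, as none of these tests passed after adjustment over the 20 lists. The smallest p of the first test is 0.005, or 0.1 when adjusted for a list alone at that value. Each test thus passes only when several lists reach a small p together.

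The spread of values over probe sets was narrower on the ATRA arrays (SD 2.117 to 2.28) than on untreated ones (2.395 to 2.401). When probe sets were put into 4 bins of like size by their level on the untreated knockout arrays, the dimmest bin changed by a median of 0.37 in wild-type cells at 48 h, with 82.3% of probe sets above 0. The brightest bin changed by −0.38, with 27.6% above 0. This is consistent with a compression of the signal scale on the ATRA arrays, and a broad change of transcripts by ATRA stays open as well. Small ATRA changes in dim or bright probe sets may therefore partly reflect the scale.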

How the results depend on the processing

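The weights per group and the replicate block within the 72 h arrays were chosen after the results had been seen, and the other alternatives before. None of the named genes that were called reversed under any alternative, and other genes were not followed one by one. Without wild-type 48 h replicate 3 the medians of 2 called lists between genotypes at 48 h changed sign, NF-kB targets to 0.086 and chemokines and cytokines from −0.18 to 0.055, and neither was called. Without knockout 48 h replicate 3 the NF-kB median was −0.44. Without knockout 72 h replicate 2 the mitosis median at 72 h became −0.14 between genotypes and −0.15 for the difference of responses, and without knockout 72 h replicate 1 it was 0.11 and 0.15. With all arrays both mitosis medians lay near 0 and were not called, and without replicate 2 both were called. The cause was not tested. With brighter probe sets only, the eosinophil, basophil and mast cell list, not called before, was called lower in each ATRA comparison, as at 72 h in wild-type cells (median −3.63 in place of 0.21). This setting drops the dimmer members of the list, and the new median equals the change given for HDC. The call thus stands for the brighter members alone.

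The genotype counts depended on the spread assumed and on single arrays. Between genotypes in untreated cells (2 probe sets) quantile normalization, the brighter probe sets only and the replicate block each left 1, while the compared groups alone gave 284 and weights per group 309 (168 higher, 141 lower). At 48 h (7 probe sets) median centring gave 3, no trend 2, and weights or the compared groups alone 0. At 72 h (32 probe sets) quantile normalization gave 53 (22 higher, 31 lower), which held all 32, weights gave 14, and the compared groups alone gave 0, with the replicate block too. As the untreated arrays vary far less than the others, a fit of all arrays calls fewer probe sets in untreated cells and more under ATRA than the compared groups alone. With the replicate block in the full fit, the paired counts were 5 at 48 h and 29 at 72 h.

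The ATRA counts fell where fewer probe sets were tested. Among brighter probe sets limma called 9603 at 72 h in wild-type cells and 8830 in knockout cells. Among probe sets of 1 gene it called 7942 and 8921 in wild-type cells at 48 and 72 h, and 8699 and 8454 in knockout cells. The probe set called for the difference of responses at 48 h was not among the brighter or the single-gene ones (0 in each), and the compared groups alone gave 2 at 48 h and 3 at 72 h. The cause of the last was not tested.

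Lists between genotypes in untreated cells (0 called) became 6 with brighter probe sets and 3 with the compared groups alone. The cause was not tested. With an estimated correlation 0 lists were called between genotypes at 48 and at 72 h and for the differences of response, and 1, the retinoid targets, in each ATRA comparison. The correlation was estimated at up to 0.736, but at 0.000473 for specific granule and −0.0662 for transglutaminase genes, whose calls at 72 h ended as well. Both estimates lie below the preset 0.01, so the size of the correlation does not account for the loss of these calls. The setting thus changes the test by more than the correlation, and what else it changes was not tested. Fry, which does not compare a list with other genes, called 0 and 7 between genotypes at 48 and 72 h, 15 and 19 for ATRA in wild-type cells, 15 and 15 in knockout cells, and 0 and 1 for the differences of response. Robust eBayes gave no list tests, since camera has no such setting.

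Leaving out each array in turn gave these ranges. Between genotypes limma called 1 to 1 in untreated cells, 1 (without wild-type replicate 3) to 13 (without knockout replicate 3) at 48 h, and 11 (without wild-type replicate 1) to 126 (without wild-type replicate 2) at 72 h. For ATRA it called 9899 to 13658 and 11492 to 13367 in wild-type cells at 48 and 72 h, and 10606 to 13731 and 10868 to 13917 in knockout cells. For the differences of response it called 1 to 2 at 48 h and 0 to 1 at 72 h. Camera called 0 to 2, 5 to 9 and 12 to 13 lists between genotypes in untreated cells, at 48 h and at 72 h. It called 8 to 10 and 9 to 12 for ATRA in wild-type cells, 5 to 8 and 7 to 7 in knockout cells, and 4 to 8 and 6 to 13 for the differences of response.

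Among the genes named for genotype, SLCO3A1 kept its call in 15 of 15 alternatives, IGF2BP2 and PADI4 at 72 h in 14 of 16, TGM2 in 7 of 15 at 48 h (adjusted p 0.00629 to 0.997) and 8 of 16 at 72 h (adjusted p 0.0102 to 0.313). The TGM2 difference stayed between −1.48 and −1.12 at 48 h and between −1.31 and −0.94 at 72 h. The pseudocount alternative was not run, as the values are already on a log scale. Median centring moved the median change of all probe sets for ATRA at 48 h in knockout cells from 0.14 to 0.06. No signal over background was used here, so absence of a dim transcript cannot be read from these values.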

Other observations

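The gene sets of this part were chosen after their values had been seen, so their counts are descriptions and not independent tests.

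Genes of antigen processing rose under ATRA in both genotypes. In wild-type cells 8 of 9 were higher at 72 h and 0 lower, and in knockout cells 7 were higher. The immunoproteasome subunits PSMB8, PSMB9 and PSMB10 changed by 3.14 ± 0.12 (SE), 3.34 ± 0.13 and 1.57 ± 0.20 in wild-type cells. TAP1, a peptide transporter, changed by 1.62 ± 0.19 and B2M, the light chain of class I molecules, by 1.10 ± 0.13. None of the 9 was called between the genotypes at 72 h, where PSMB9 read −0.28 (adjusted p = 0.45) and TAP1 −0.54 (adjusted p = 0.302).

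Metallothioneins, which bind zinc and copper, fell. In wild-type cells 6 of 8 measured members were lower at 72 h and 0 higher, and in knockout cells 5 were lower. MT1F changed by −2.12 ± 0.11, MT2A by −1.99 ± 0.17 and MT1X by −1.77 ± 0.22 in wild-type cells. Of the 5 peptidylarginine deiminases, PADI2 rose 16.6-fold (4.06 ± 0.25), PADI4 by 2.98 ± 0.12 and PADI3 by 0.69 ± 0.12. PADI2 read −0.18 between the genotypes at 72 h (adjusted p = 0.858), against −0.94 for PADI4.

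IL1B, which encodes interleukin 1 beta, was high on some arrays of wild-type cells only. It read 7.64 on replicate 3 at 48 h, and 7.59 and 7.42 on replicates 1 and 3 at 72 h. The other 15 arrays lay between 5.43 and 6.01.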
